A study of Mus musculus with 6 samples.

How the data were processed

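ChIP-seq peak lists of 5 of the 6 samples were used: EWS-FLI1 (FLAG antibody) and H3K27ac in ES48 and ES49, and H3K27me3 in ES49. Reads were aligned to mm9 with Bowtie 1.1.1 and handled with SAMtools 1.2, per the submitters' processing notes. The peak names point to a MACS program; its version, settings, control and filters are not given in the sources used here. Each deposited list gives chromosome, start, end, a peak name and a score per peak, the caller's own. The scores start at 50 and level off at 3100 to 3233.1, as a multiple of the −log10 of a p-value would. That scale is inferred from the values and is not stated, so scores were compared only within a list. Read counts are not in the lists, so depth is unknown.

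Peaks overlapped when they shared at least 1 bp, and a shared peak is one that overlaps a peak of the same antibody in the other line. For each overlap, the peaks of one list were placed at random 1000 times on their own chromosome, with their widths, between the first and last peak start of any list. The two-sided permutation p is at least 0.0020. Shares carry 95% Clopper-Pearson intervals. Counts were compared with Fisher's exact test, odds ratios with Zelen's exact test and medians with permutation tests of 100000 resamples, all two-sided with a threshold of 0.05. H3K27ac peaks less than 12.5 kb apart were joined, and domains were ranked by the length covered by peaks. The p-values and intervals concern counting error within single libraries. Neighbouring peaks are not independent, so the intervals are too narrow and the p-values too small even for that. The family of 21 tests includes ES48 lists against ES49 H3K27me3, planned as a description for EWS-FLI1 and not planned for H3K27ac. Of the 21 tests, 18 had a Benjamini-Hochberg adjusted p below 0.05, and the raw permutation p of 0.0020 became 0.00262. The 3 others were the ES48 H3K27ac overlap with ES49 H3K27me3 (adjusted permutation p = 0.267), line-specific binding against line-specific acetylation (adjusted exact p = 0.686) and the ES49 H3K27ac width (adjusted permutation p = 0.929).

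The regions named were set before the data were examined, as were most tests and alternatives: the 10 highest-scoring peaks of each list, the 10 shared EWS-FLI1 peaks ranked highest over both lists and the 5 H3K27ac domains per line with the most covered length. The dense loci (EWS-FLI1 peaks of both lines joined at less than 500 kb, with at least 10 peaks), every result without them, and other regions marked in the text were chosen after the data were seen. Alternatives were an overlap of 50% of the shorter peak, peaks within 1 kb, the upper 50% by score, placement within 50 to 500 kb, autosomes alone, lists of equal length, leaving out the 1% widest and highest peaks, joining at 5 kb and ranking by summed score. In each overlap the cut by score was made in both lists.

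The overlap test was run on simulated data, with 200 placements per run. The simulated lists were drawn by the same independent placement that the test uses, so few significant runs without planted peaks were built in. Real EWS-FLI1 peaks crowd together, and the runs do not show how the test behaves for such lists. With ES48 EWS-FLI1 peaks placed at random against H3K27ac, 3 of 50 runs were significant, and with 60 peaks planted 50 of 50 were. For ES49 the numbers were 2 of 50 and 50 of 50 with H3K27ac, and 0 of 50 and 50 of 50 with H3K27me3. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

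The gene table at hand is of GRCm38, and 402 H3K27ac peaks lie past the last GRCm38 gene of their chromosome, so it was not used with mm9 positions. The planned tests of peak location, promoters of gene lists, EWS-FLI1 near gene lists, and ETS and GGAA motifs need an mm9 annotation or sequence and were not run. The ES49 input sample was not analysed here.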

Results

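The series mapped the fusion protein EWS-FLI1 and histone H3 marks by ChIP-seq in ES48 and ES49, mouse cell lines of EWS-FLI1-induced Ewing sarcoma on a Balb/c background. EWS-FLI1 was precipitated through its FLAG tag and H3K27ac, a mark of active promoters and enhancers, was precipitated in both lines. H3K27me3, the mark laid down by Polycomb repressive complexes, was precipitated in ES49 alone. The 6 samples form 6 groups of 1, the last being ES49 input DNA, which has no peak list among the data used here. There is no biological replication, so every test below is over peaks within these libraries and every interval covers counting error only. The intervals treat peaks as independent, and peaks that lie in runs make them too narrow even for that. The files give no read counts, so the depth of each library is unknown. All positions are in mm9, and regions are named by position because no annotation of that build was used.

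The EWS-FLI1 lists were short and their peaks narrow. ES48 had 614 EWS-FLI1 peaks with a median width of 183 bp, and ES49 had 681 with a median width of 230 bp. H3K27ac gave 25970 peaks covering 48.3 Mb in ES48 and 29652 peaks covering 35.8 Mb in ES49, with median widths of 1475 and 838 bp. H3K27me3 gave 19560 peaks covering 16.6 Mb in ES49. In the ES48 EWS-FLI1 list 41.2% of the peaks had a score below 60, close to the lowest score of 50.1. In the ES49 list 14.5% did. The scale of the scores is not stated, so these shares describe each list on its own.

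EWS-FLI1 peaks were unevenly spread over the chromosomes. Chromosomes X and Y held 33.2% of the ES48 EWS-FLI1 peaks (95% Clopper-Pearson interval 29.5 to 37.1) and 50.8% of those in ES49 (47.0 to 54.6). The same chromosomes held 2.53% of the ES48 H3K27ac peaks, 2.17% of the ES49 H3K27ac peaks and 0.757% of the ES49 H3K27me3 peaks. Chromosome Y alone had 133 EWS-FLI1 peaks in ES48 and 105 in ES49. H3K27me3 peaks were densest among the autosomes on chromosome 11, at 23.3 per Mb, and chromosome X had 0.484 per Mb.

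**Figure D1:**
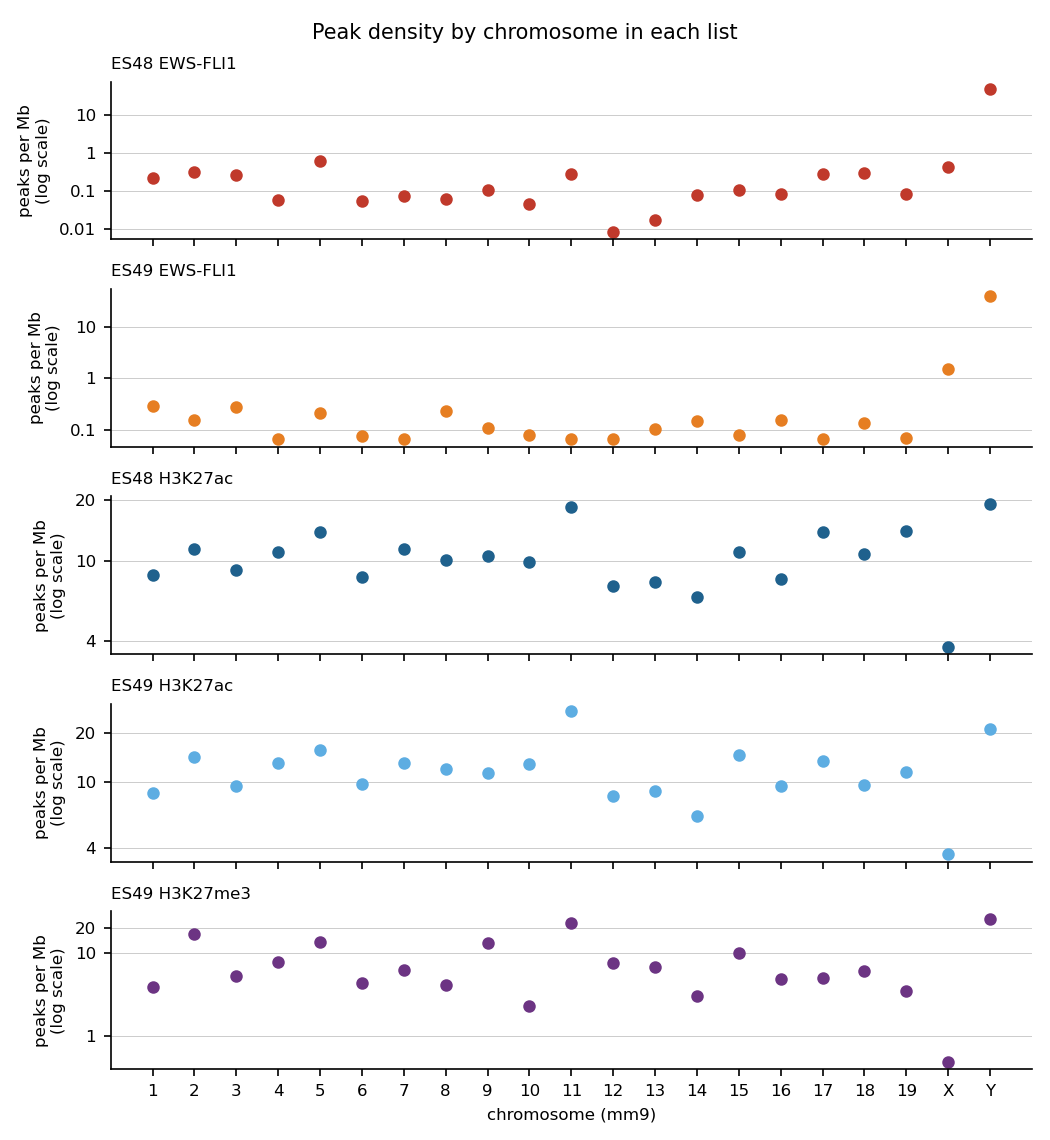
Peaks per Mb of chromosome span (log scale, with its own range in each panel) for each of the 5 lists, by chromosome in mm9; each point is 1 list on 1 chromosome. EWS-FLI1 peaks are densest on Y, at 49.9 per Mb in ES48 and 39.4 in ES49. H3K27me3 peaks are densest on Y too, at 26.2 per Mb, and sparsest on X.

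Much of the unevenness of EWS-FLI1 came from 11 short loci, defined after the data were seen as runs of at least 10 EWS-FLI1 peaks of either line less than 500 kb apart, and called dense loci here. They span 4.92 Mb, 0.191% of the genome span, and held 225 of the ES48 EWS-FLI1 peaks (36.6%, 32.8 to 40.6) and 419 of the ES49 peaks (61.5%, 57.8 to 65.2). The locus at chromosome Y 2477090 to 2902430 held 114 ES48 and 71 ES49 EWS-FLI1 peaks, with 41 ES48 H3K27ac, 48 ES49 H3K27ac and 64 ES49 H3K27me3 peaks. The locus at chromosome X 120112393 to 121325137 held 58 ES48 and 173 ES49 EWS-FLI1 peaks. The overlaps of EWS-FLI1 with each mark and between the lines are therefore given with and without the dense loci.

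**Figure D2:**
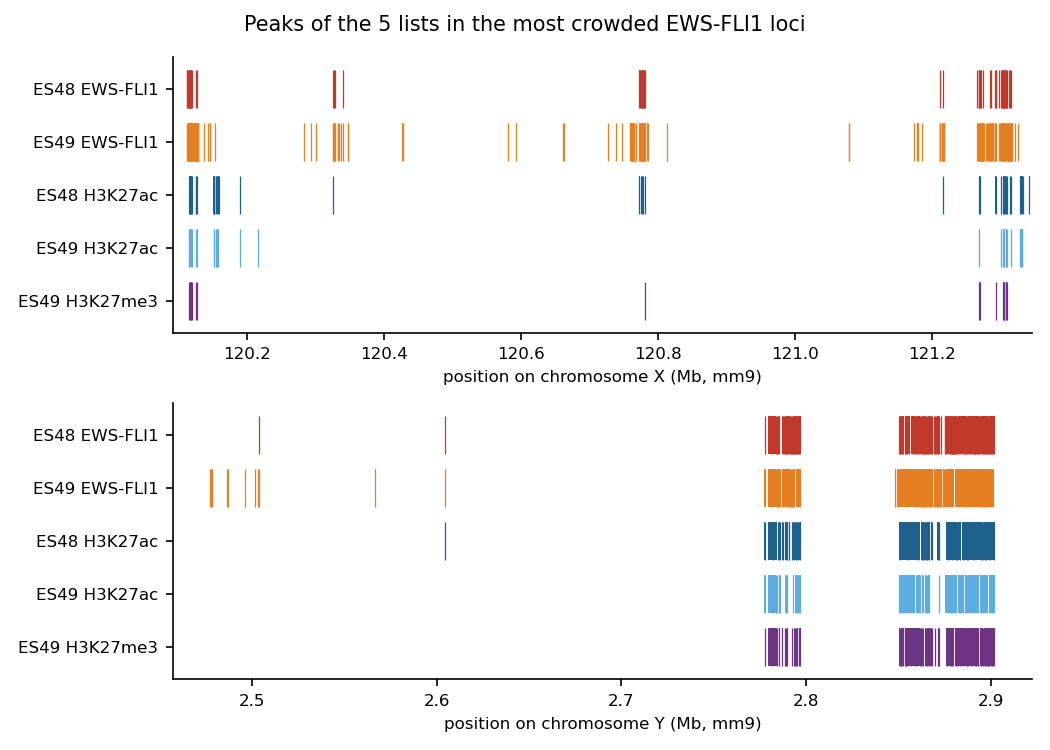
Peaks of the 5 lists (rows) along the dense loci of chromosomes X and Y with the most EWS-FLI1 peaks, against position in Mb of mm9; each bar is 1 peak, drawn with a line at its middle so that narrow peaks stay visible. On Y the peaks of all 5 lists stack at the same places toward the right end, while on X many ES49 EWS-FLI1 peaks have no peak of another list.

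The first comparison asked how far EWS-FLI1 binding was shared by the lines. In ES48 271 of 614 EWS-FLI1 peaks (44.1%, 40.2 to 48.2) overlapped an ES49 peak, and in ES49 189 of 681 (27.8%, 24.4 to 31.3) overlapped an ES48 peak. Shared peaks scored higher, with a median of 147.1 against 56.7 for line-specific peaks in ES48 and 357.3 against 86.6 in ES49. The 10 shared peaks ranked highest over both lists included 8 on chromosome Y, such as 2856663 to 2858817 and 2779625 to 2783091 in ES48. The others lay at chromosome X 121307056 to 121307694 and chromosome 17 39979938 to 39983636. All 20 of the highest-scoring EWS-FLI1 peaks, 10 per line, overlapped peaks of the remaining 4 lists, H3K27me3 included. Random placement of the peaks on their own chromosomes gave a mean of 4.87 shared peaks for ES48 and 3.14 for ES49, and the two-sided permutation p was 0.0020 in each direction, the smallest that 1000 placements can give. The permutation p for the scores was 1e-05 in each line, the smallest that 100000 resamples can give, and it was the same without the dense loci, where the medians were 113.6 against 56.6 in ES48 and 187.5 against 78.6 in ES49. Outside the dense loci, 53 of 389 ES48 peaks (13.6%) and 51 of 262 ES49 peaks (19.5%) were shared, and on autosomes alone 17.1% and 18.5% were. The gap between the lines closed when peaks within 1 kb counted as shared, at 45.4% in ES48 and 44.2% in ES49, and with the upper 50% by score the shares were 76.6% and 47.5%. Counted by locus, with peaks of both lines joined as above, 55 of 430 loci (12.8%) held overlapping peaks of both lines.

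Outside the dense loci, shared EWS-FLI1 peaks met H3K27me3 more often than line-specific peaks. In ES48 14 of 53 shared peaks and 15 of 336 line-specific peaks overlapped ES49 H3K27me3 (26.4% against 4.46%, Fisher's exact p = 2.40e-06). In ES49 the counts were 13 of 51 and 2 of 211 (25.5% against 0.948%, Fisher's exact p = 1.13e-08). Shared peaks with every mark included chromosome 17 36621512 to 36621929, chromosome 9 13422531 to 13422875, chromosome 2 22600340 to 22600450 and chromosome 5 80242460 to 80242738. Shared peaks with neither histone mark included chromosome 18 7321315 to 7321512 and chromosome 2 98177181 to 98177276. This split was made after the data were seen. Peaks of all 5 lists met at 10 places outside the dense loci. Reads that gather at some places whatever the antibody may therefore account for the higher shares, and this was not tested here.

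The next comparison asked whether EWS-FLI1 lay in acetylated chromatin. In ES48 211 of 614 EWS-FLI1 peaks (34.4%, 30.6 to 38.3) overlapped H3K27ac of the same line, against a mean of 14.01 for placed peaks. In ES49 134 of 681 (19.7%, 16.8 to 22.9) did, against 9.93. The permutation p was 0.0020 in each line. Many of these places were called for both marks: of the 211 ES48 peaks 138 also overlapped ES49 H3K27me3, and of the 134 ES49 peaks 58 did. In the dense loci 124 of 152 such ES48 peaks and 48 of 63 such ES49 peaks did. The ES49 share was 12.0% with the upper 50% of both lists by score, a cut that also takes away H3K27ac peaks to overlap. With peaks within 1 kb it was 30.3%. On autosomes alone the order of the lines turned, with shares of 16.3% in ES48 and 23.3% in ES49. The order turned without the dense loci too. Outside them 59 of 389 ES48 peaks (15.2%, 11.8 to 19.1) and 71 of 262 ES49 peaks (27.1%, 21.8 to 32.9) overlapped H3K27ac. The placed means were 9.69 and 4.46. Of the 71 ES49 peaks, 61 met H3K27ac without H3K27me3, and of the 59 in ES48, 45 did.

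Among these, chosen after the data were seen, chromosome 5 142500372 to 142501309 in ES49 lay in a 5055 bp H3K27ac peak with a score of 3100, and ES48 had an EWS-FLI1 peak at 142500592 to 142501002 in a 9731 bp H3K27ac peak. Chromosome 4 154247180 to 154247650 had EWS-FLI1 in ES49 alone, in a 4442 bp H3K27ac peak, and the place was acetylated in both lines. At chromosome 5 105356873 to 105357229 the ES49 EWS-FLI1 score was 998.7 and the H3K27ac peak was weaker, with a score of 100.5. In ES48 the highest-scoring EWS-FLI1 peaks of this kind, at chromosome X 51325253 to 51325337 and chromosome 13 97960493 to 97960593, met H3K27ac peaks of 183 and 367 bp.

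**Figure D3:**
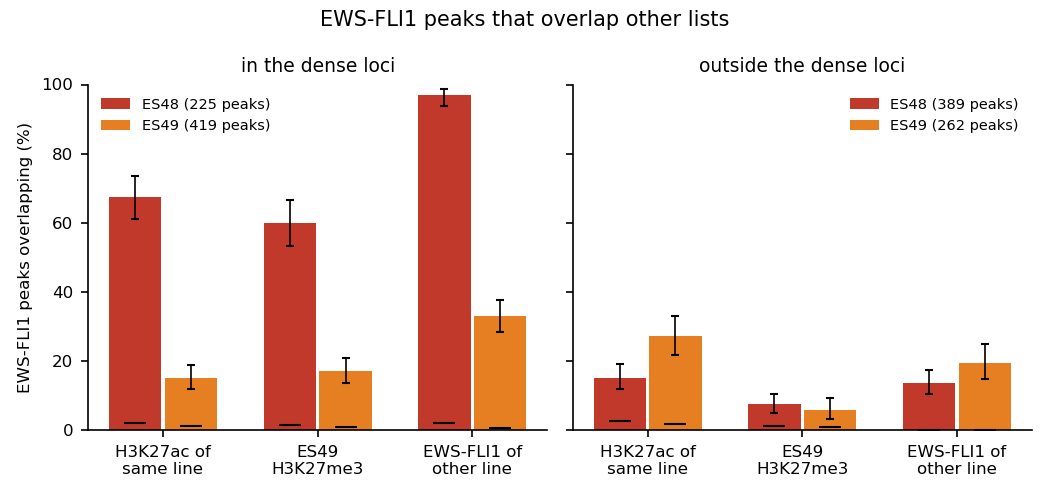
Percent of EWS-FLI1 peaks (y axis) that overlap H3K27ac of the same line, ES49 H3K27me3 or EWS-FLI1 of the other line, in ES48 and ES49, inside and outside the dense loci; bars are observed shares, error bars 95% Clopper-Pearson intervals and short black lines the mean share of random placements. In the dense loci 67.6% of ES48 peaks and 15.0% of ES49 peaks overlap H3K27ac, and outside them 15.2% and 27.1%.

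H3K27ac was more frequent at shared than at line-specific EWS-FLI1 peaks. In ES48 183 of 271 shared peaks (67.5%) and 28 of 343 line-specific peaks (8.16%) overlapped H3K27ac, an odds ratio of 23.4 (Fisher's exact p = 7.05e-57). In ES49 71 of 189 (37.6%) and 63 of 492 (12.8%) did, an odds ratio of 4.10 (Fisher's exact p = 3.39e-12). Without the dense loci the odds ratio was 17.4 in ES48 and 1.45 in ES49, where the difference no longer passed the test (17 of 51 against 54 of 211, Fisher's exact p = 0.293). With the upper 50% of each list by score the odds ratio was 2.35 in ES48 and 3.03 in ES49, so the order of the lines turned.

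Line-specific EWS-FLI1 peaks seldom lay in line-specific H3K27ac. Their median scores were 56.7 in ES48 and 86.6 in ES49, against a lowest score of 50.1 in each list. Weak calls may therefore lower the shares below, most of all in ES48, and this was not tested. Of 343 ES48-only EWS-FLI1 peaks, 310 lay in H3K27ac of neither line, 19 in H3K27ac of both, 9 in ES48 alone and 5 in ES49 alone. Of 492 ES49-only peaks, 421 lay in neither, 61 in both, 8 in ES48 alone and 2 in ES49 alone. Acetylation in a single line did not go detectably with binding in that line (odds ratio 0.450, Fisher's exact p = 0.653), with 24 peaks in the table. Without the dense loci the test was not passed either: of the peaks acetylated in a single line, 9 of 14 ES48-only and 4 of 4 ES49-only EWS-FLI1 peaks were acetylated in ES48 (Fisher's exact p = 0.278). Of 336 ES48-only peaks there, 9 lay in H3K27ac of ES48 alone, 5 in ES49 alone and 18 in both. Outside the dense loci, of 211 ES49-only peaks 54 lay in H3K27ac of both lines and 0 in H3K27ac of ES49 alone.

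H3K27ac peaks that held EWS-FLI1 were compared with the rest of their list. In ES48 the 132 H3K27ac peaks with EWS-FLI1 had a median width of 637.5 bp against 1478 bp (permutation p = 1e-05), and lower scores (206.1 against 550.2, permutation p = 0.0347). In ES49 the 140 such peaks had widths of 848 against 838 bp (permutation p = 0.929) and scores of 279.2 against 165.7 (permutation p = 0.0142), a difference that did not pass the test without the 1% widest and highest peaks (179.1 against 160.7, permutation p = 0.614) and was larger without the dense loci (847.3 against 165.7, permutation p = 1e-05). The direction in ES48 turned without the dense loci, to 2664 against 1479 bp, and in ES49 the widths were 1851 against 838 bp (permutation p = 1e-05 in each). The ES48 scores were then 950.5 against 551.8 (permutation p = 0.0923), which did not pass the test. Wide peaks are hit more often by chance, which a comparison with the rest of the list does not take into account. With all peaks, H3K27ac peaks hit by placed EWS-FLI1 peaks had median widths of 2357 bp in ES48 and 1417 bp in ES49. The observed 637.5 and 848 bp were both narrower. Outside the dense loci the placed values were 2557 bp in ES48, near the observed 2664, and 1570 bp in ES49, against 1851 observed. Observed and placed widths were not tested against each other.

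EWS-FLI1 peaks also overlapped H3K27me3. In ES49 86 of 681 EWS-FLI1 peaks (12.6%, 10.2 to 15.4) overlapped H3K27me3, against a mean of 5.59 for placed peaks, and 164 of 614 ES48 peaks (26.7%, 23.3 to 30.4) lay in ES49 H3K27me3, against 7.49. The permutation p was 0.0020 in each. Of the 86 ES49 peaks, 58 overlapped H3K27ac as well. Without the dense loci the counts were 15 of 262 (5.73%, placed mean 2.26) and 29 of 389 (7.46%, placed mean 4.26). On autosomes alone the shares were 8.66% in ES49 and 10.7% in ES48, and with peaks within 1 kb the ES49 share was 23.9%. The ES48 comparison is across lines, since H3K27me3 has a list in ES49 alone.

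Acetylation was largely common to the lines. In ES48 17303 of 25970 H3K27ac peaks (66.6%, 66.1 to 67.2) overlapped an ES49 peak, and in ES49 20327 of 29652 (68.6%, 68.0 to 69.1) overlapped an ES48 peak, against placed means of 866.6 and 954.7 (permutation p = 0.0020 in each). Shared H3K27ac peaks were wider, with a median of 1953 bp (quartiles 1195 and 2824) against 690 bp (485 and 1178) in ES48 and 1243 bp against 457 bp in ES49. Among the 10 highest-scoring H3K27ac peaks of ES48, 9 were shared, including chromosome 4 124333225 to 124338451 and chromosome 5 96759700 to 96763487, and chromosome 6 138365575 to 138372508 was absent from the ES49 list. All 10 of ES49 were shared, among them chromosome 1 156100201 to 156106888 and chromosome 15 63828436 to 63830529. None of these 20 overlapped EWS-FLI1 or H3K27me3. With peaks moved by 50 to 500 kb in place of anywhere on the chromosome, the excess over placement fell from 19.97-fold to 8.48-fold in ES48 and from 21.3-fold to 8.73-fold in ES49.

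Joining neighbouring H3K27ac peaks gave 13750 domains in ES48 and 13484 in ES49, and 47 of the 100 with the most covered length in each line overlapped 1 of the other line's 100 (placed means 1.06 and 1.04, permutation p = 0.0020). The domain at chromosome 5 120940333 to 121079224 came first in ES49, with 93.9 kb covered, and its counterpart at 120940496 to 121039851 came second in ES48, with 61.8 kb. The first in ES48 was chromosome 4 132566460 to 132688919, with 76.3 kb covered in ES48 and 52.6 kb in ES49. The domain at chromosome 11 98568674 to 98672623 in ES48 matched 98542953 to 98672120 in ES49. Chromosome 10 79440935 to 79642877 and chromosome 11 74947274 to 75087171 were among the first 5 of ES49. Of the 100 domains per line, 5 in ES48 and 6 in ES49 held an EWS-FLI1 peak of their line, against placed means of 1.36 and 0.868. With domains ranked by summed score the counts were 2 and 5, against 1.27 and 0.801, and these counts were not tested.

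H3K27ac and H3K27me3 were largely apart in ES49. Of 29652 H3K27ac peaks, 264 (0.890%, 0.787 to 1.004) overlapped H3K27me3, against a placed mean of 440.4, a ratio of 0.600 (permutation p = 0.0020), which was 0.315 with peaks moved by 50 to 500 kb. The 2 marks shared 186.3 kb, 0.520% of the length covered by H3K27ac. The ES48 H3K27ac peaks showed no detectable difference from placement in ES49 H3K27me3, with 451 against 426.7 (ratio 1.06, permutation p = 0.242). That ratio fell below 1 under other settings, and passed the threshold at 0.604 (permutation p = 0.0020) with peaks moved by 50 to 500 kb and at 0.906 (permutation p = 0.0360) without the dense loci. The highest-scoring H3K27me3 peaks included chromosome 3 87600254 to 87609991, chromosome 6 52173920 to 52187190 and chromosome 2 74558876 to 74568111. Of the 10 highest, that on chromosome 6 overlapped H3K27ac of both lines and chromosome 11 103510025 to 103518065 overlapped H3K27ac of ES48.

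**Figure D4:**
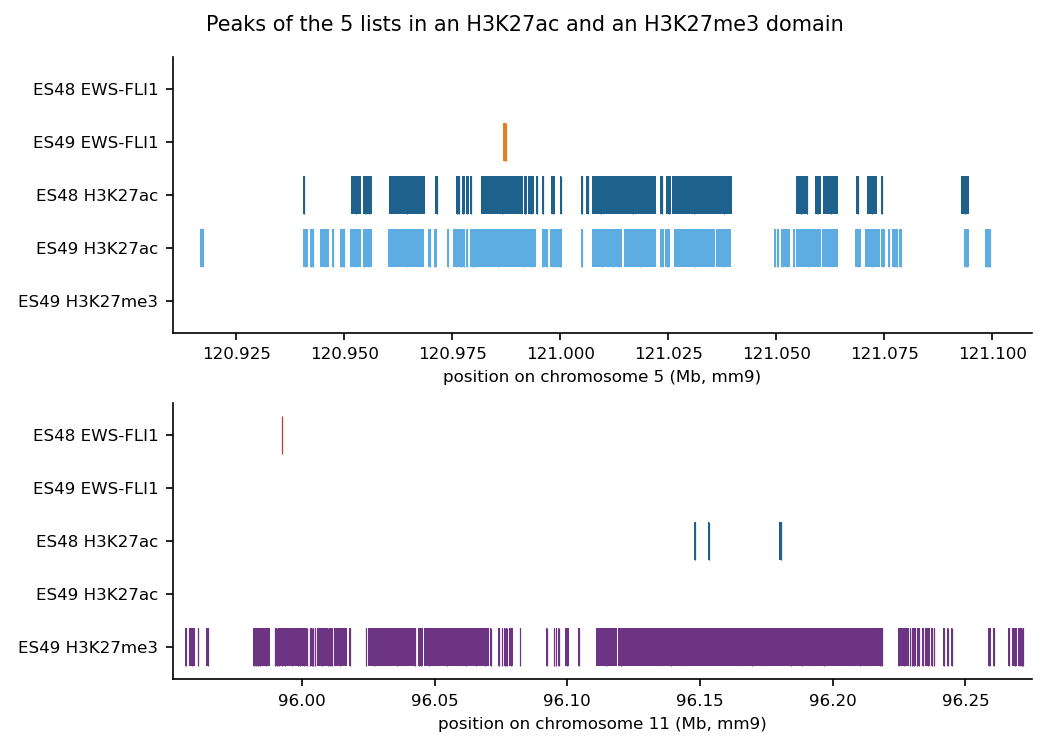
Peaks of the 5 lists (rows) along the ES49 H3K27ac domain with the most covered length, on chromosome 5, and the ES49 H3K27me3 domain with the most covered length, on chromosome 11, against position in Mb of mm9; each bar is 1 peak. The first holds 51 ES49 and 33 ES48 H3K27ac peaks and no H3K27me3, and the second holds 73 H3K27me3 peaks and no ES49 H3K27ac.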

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

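The tests chosen only after the result was seen are those of the dense loci with both histone marks, of histone peak density there, of DNA copies of chromosome 5, and every result without the dense loci except the share of higher-scoring peaks on chromosome 5; no test of ES48 against ES49 in this part was planned. The lines differed in several EWS-FLI1 results under the same comparison, each by an exact test. These tests count peaks, and the lists split the same stretch differently. The ES49 peak at chromosome Y 2849573 to 2858876 spans many ES48 peaks, from 2850418 to 2850574 up to 2856663 to 2858817. Such peaks are not independent, so the p-values below do not measure a difference between the lines as such. ES48 EWS-FLI1 peaks overlapped H3K27ac more often than ES49 peaks (34.4% against 19.7%, Fisher's exact p = 2.80e-09), and less often without the dense loci (15.2% against 27.1%, Fisher's exact p = 0.000296). The odds ratio of H3K27ac at shared against line-specific peaks was higher in ES48 than in ES49, with Zelen's exact p = 1.75e-08 for all peaks and 2.35e-07 without the dense loci. With the upper 50% by score the order turned, to 2.35 in ES48 and 3.03 in ES49, and that difference was not tested. ES48 EWS-FLI1 peaks overlapped ES49 H3K27me3 more often than ES49 peaks (26.7% against 12.6%, Fisher's exact p = 1.56e-10), a difference that did not pass the test without the dense loci (7.46% against 5.73%, Fisher's exact p = 0.429). The dense loci held 36.6% of the ES48 and 61.5% of the ES49 EWS-FLI1 peaks (Fisher's exact p = 3.57e-19). They were chosen by the EWS-FLI1 peaks of both lines pooled, so this test uses the peaks that defined them. Chromosome 8 71942562 to 72129497, for example, held 0 ES48 and 10 ES49 peaks, and chromosome Y 2477090 to 2902430 held 114 and 71. Outside the dense loci, chromosome 5 held 91 of 382 autosomal ES48 peaks and 32 of 236 in ES49 (Fisher's exact p = 0.00184). Chromosome 5 had the most such peaks of the autosomes in both lists, and the p is not adjusted for a choice among 19 autosomes. Chromosomes 11 and 17 also had more peaks in ES48 than in ES49 (33 against 8 and 27 against 6). Chromosomes 13 and 14 had fewer (2 against 12 and 10 against 18).

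EWS-FLI1 peaks crowded into 11 dense loci, and weak calls are argued against, since these loci held a larger share of the upper 50% by score than of all peaks in both lines, by a factor of 1.18 in ES49 and more in ES48. Reads that gather there whatever the antibody may be the source: H3K27me3 peaks were 2.85 times as dense there as elsewhere (95% interval 2.33 to 3.44), but ES49 H3K27ac peaks were 1.66 times as dense, short of the factor of 2 set for both ES49 marks (ES48 H3K27ac, outside that rule, was at 2.18), so the explanations cannot be told apart. In the 6 autosomal dense loci the factors were 1.34 for H3K27me3 (0.794 to 2.12) and 0.846 for ES49 H3K27ac (0.493 to 1.35). For ES48 H3K27ac the factor was 1.26 (0.786 to 1.90). These loci differ: chromosome 2 27351241 to 27358306 held 5 H3K27me3 peaks and 4 H3K27ac peaks in each line. Chromosome 3 25417087 to 25456256 held 0 H3K27me3 peaks and 1 H3K27ac peak in each line. The EWS-FLI1 factors, 605.2 in ES49 and 105.7 in ES48, were raised by the choice of the loci and are no evidence on the source. The H3K27me3 interval holds the factor of 2 as well as no excess, so the autosomal values do not decide. Computed after that test fell short, 62 of 77 ES49 H3K27ac peaks in the dense loci of X and Y (80.5%, 69.9 to 88.7) and 5 of 17 in the autosomal ones (29.4%, 10.3 to 56.0) overlapped H3K27me3, against 0.667% elsewhere, which goes with shared read pile-up without settling it. EWS-FLI1 binding in these loci stays open as the biological explanation, untested without an untagged FLAG control or input peaks.

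ES48 EWS-FLI1 peaks outside the dense loci crowded onto chromosome 5, with 23.8% of the autosomal peaks (19.6 to 28.4) on 6.20% of the autosomal span. In ES49 13.6% lay there, also above that share of the span. Calls with a score below 60 as the only source are argued against, since of peaks with a score of 60 or more 20.1% (13.9 to 27.6) lay there. Of peaks below 60, 26.05% (20.6 to 32.1) did. A score of 60 is itself not far above the lowest of 50.1, so weak calls above it are not tested. More copies of chromosome 5 in ES48 than in ES49 may contribute. The log2 ratio of ES48 to ES49 H3K27ac peaks there was -0.17, which is 0 from the median of the 19 autosomes, with an SD of 0.20. Chromosome 5 is itself that median, and the value of 0 meets the rule set for no gain, a ratio at or below the median. Peak counts level off with depth, however, so a gain still cannot be told apart from none. The control of the ES48 list is not given, and with input of another line as control such a gain could itself yield peaks, a point that the value of 0 does not settle. No biological explanation was tested.

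ES49 had more H3K27ac peaks relative to ES48 where its H3K27me3 peaks were many, over 249 bins of 10 Mb (Spearman's rho 0.485, Pearson's r 0.463, permutation p = 0.0001 by rotating bins, the smallest 10000 rotations give). Bins are not independent replicates. With the upper 50% of each H3K27ac list by score rho was 0.315, and given the ES48 H3K27ac density, with which the ratio of the lines correlated as strongly (rho 0.484), it was 0.260. Each is lower than with all peaks and neither fell to 50% of it, so weak ES49 peaks and a shared density along the chromosomes may each account for part and cannot be told apart. A biological difference between the lines stays open as well, as untested.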

How the results depend on the processing

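Of 100 alternative values, 88 kept their direction and their side of the threshold, 2 were weaker, 1 was stronger, 8 reversed and 1 moved. The ratio of ES48 H3K27ac peaks in ES49 H3K27me3 to placement, 1.06, reversed to 0.978 with peaks within 1 kb, 0.991 with the upper 50% by score, 0.604 with peaks moved by 50 to 500 kb, 0.920 on autosomes and 0.906 without the dense loci. The main value did not differ detectably from placement, and the values of 0.604 and 0.906 did. Without the 1% widest and highest peaks, the width difference of ES49 H3K27ac peaks with EWS-FLI1 reversed to -62 bp and the score difference weakened to 18.4 and no longer passed the threshold (permutation p = 0.614). Without the dense loci, an alternative chosen after seeing the data, the ES48 width and score differences reversed to 1185 bp (permutation p = 1e-05) and 398.7 (permutation p = 0.0923, not past the threshold), the ES49 width difference strengthened to 1013 bp, the ES49 odds ratio of H3K27ac at shared EWS-FLI1 peaks weakened to 1.45 and no longer passed the threshold, and 1 of the 10 highest shared EWS-FLI1 peaks was left. The cause was not tested. The width differences are from the rest of the list and not from H3K27ac peaks hit by placed EWS-FLI1 peaks, which were wide in ES48 too (median 2557 bp without the dense loci). Shared EWS-FLI1 peaks stayed above placement under every alternative run, from 34.3-fold with peaks within 1 kb up to values that rest on placed means near 0 on autosomes or without the dense loci, for which counts are the safer guide. ES49 H3K27ac stayed below placement in H3K27me3 throughout (0.315 to 0.632). The alternatives planned for location, gene lists and motifs could not be run without mm9 annotation and sequence. Read depth is unknown, so differences in list length between the lines may reflect depth.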

Other observations

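The values here on ES48 H3K27ac that lies in ES49 H3K27me3, and the tests on them, were not planned; the first test of EWS-FLI1 at such peaks was fixed before its result was seen and those that follow it were chosen after. Of 8667 H3K27ac peaks found in ES48 alone, 256 (2.95%, 2.61 to 3.33) lay in ES49 H3K27me3, against 195 of 17303 shared peaks (1.13%, 0.975 to 1.30; odds ratio 2.67, Fisher's exact p = 1.33e-24). The odds ratio was 3.46 without the dense loci and 7.56 with the upper 50% by score. Shared peaks overlap ES49 H3K27ac by definition, and that mark met ES49 H3K27me3 less often than placed peaks (ratio 0.600), so an odds ratio above 1 in part restates the separation of the marks within ES49 and is no separate evidence of a change between the lines. The longest run by acetylated length was at chromosome 1 74818060 to 74855886, with 6 such peaks covering 16.2 kb. Others were chromosome 2 93011439 to 93032645, with 5 peaks covering 11.6 kb, and chromosome 11 71942702 to 71949225, with 3 peaks covering 5.15 kb. The highest-scoring of these peaks included chromosome 8 73015627 to 73020342, chromosome 12 15818512 to 15823996 and chromosome 12 62623376 to 62628626, and none of these held EWS-FLI1.

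The ES49 H3K27me3 domains with the most covered length were on chromosome 11, at 95981446 to 96245101 (204.8 kb covered) and 118468037 to 118857900 (198.5 kb). They were followed by chromosome 5 122323502 to 122522948 (133.0 kb) and chromosome 2 164901852 to 165095169 (130.3 kb). The first held 3 ES48 H3K27ac peaks and 1 ES48 EWS-FLI1 peak, and no ES49 peak of either kind.

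A hypothesis was that EWS-FLI1 marks the ES48 H3K27ac peaks that lie in ES49 H3K27me3. Outside the dense loci 14 of 386 such peaks held ES48 EWS-FLI1, against 41 of 25476 others (odds ratio 23.4, Fisher's exact p = 5.38e-14), as the hypothesis required. Of those 14, however, 11 (78.6%, 49.2 to 95.3) overlapped ES49 H3K27ac too, so they are not places that differ in acetylation between the lines. Among H3K27ac peaks of ES48 alone, 3 of 243 in H3K27me3 and 13 of 8388 others held EWS-FLI1 (odds ratio 8.05, Fisher's exact p = 0.00941), which rests on 3 peaks. Peaks of all 5 lists met at 133 places, 10 of them outside the dense loci. Reads that gather at some places whatever the antibody may therefore account for the odds ratio of 23.4, and the test does not part that from EWS-FLI1 binding.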
